A study of Homo sapiens with 5 samples.

How the data were processed

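Pseudouridine (Ψ), an abundant modified base of RNA, was measured in polyA RNA of HEK293T cells, a line derived from human embryonic kidney, with PRAISE, an assay in which a chemical treatment makes reverse transcriptase skip Ψ, so that the base is read as a deletion. The labels name 5 samples, which are 1 untreated library (mock), 2 libraries treated with gctrl and 2 libraries treated with RESTART v3. RESTART is a tool that uses a guide RNA to turn the uridine of a premature stop codon into Ψ. The table analysed here holds values of 3 of the libraries, the mock library and both RESTART v3 libraries, and the gctrl libraries are not analysed here. Nothing in the labels says that the 2 RESTART v3 libraries came from separate cultures. The p-values of the coverage models therefore measure the spread between these libraries, which may be technical. Those of the deletion model rest on counting error only, for a reason given below.

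Each entry of the table is a position of 1 to 4 nucleotides on a RefSeq transcript. Per the file headers, the deposited counts are the reads covering the position and the reads with a deletion in each library. The deletion ratio that the authors deposited is a fraction, and recomputing deleted reads over covering reads gave the same value at every position (largest gap 5.83e-16). The fraction in mock was subtracted by the authors, per the file headers, to give a difference for each RESTART v3 library. The authors also deposited a p-value for each RESTART v3 library. Of those 670 p-values, 418 equalled a one-sided Fisher exact test and 228 a chi-square test with continuity correction, both against mock, to a relative tolerance of 0.0001. Trim Galore and UMI-tools 1.0.0 and the builds hg38 and GRCh38 are named in the submitters' processing notes. The aligner and the caller of deletions are not given in the sources used here. One cell, a read total of ARL6IP4, held text in place of a number and was recomputed as 935 from the deleted reads and the deposited ratio.

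The list was selected on the outcome. The mock deletion percentage reached at most 0.950%, the authors' difference was at least 0.2 in each RESTART v3 library, and every position had at least 30 deleted reads in each of them. All positions are therefore higher in RESTART v3 by construction, a fall is not observable, and p-values over the list are not independent of the selection. A minimum of 30 deleted reads also means that a position with fewer than 150 reads enters only at a ratio above the 0.2 limit.

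Gene names were taken from the table. Of 40 positions with no name there, 36 were named through their transcript accession in the RefSeq table of GRCh38.p14, which also gave the gene coordinates, and 4 stayed unnamed. The list repeats genes across isoforms, so 1 transcript per gene was kept for comparisons across genes (the one with most listed positions, then most mock reads), which left 233 positions in 221 genes. Positions are on mature transcripts, hence exonic. Their coding, UTR or stop codon place, the stop triplet, synthase motif and sequence word questions were planned and not run, because 11 of 335 positions (3.28%) had a transcript of the same accession and version paired in GENCODE 29, under the 80% needed.

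The comparison of RESTART v3 with mock was a quasi-binomial model per position on deleted and undeleted reads, with the deviance F test, the dispersion moderated by limma 3.58.1 and not allowed below 1, and Benjamini-Hochberg adjustment at 0.05. It was run in R 4.3.3 with a coverage minimum of 20 reads. The mock library was assumed to vary like the RESTART v3 libraries. The dispersion lay at its lower limit of 1 at every position, so the replicate spread did not enter the deletion F values. With 1 against 2 libraries there are 3 splits, so an exact permutation test cannot give a p under 0.333. The tests planned between RESTART v3 and gctrl, and between gctrl and mock, were not run. Read coverage was compared between RESTART v3 and mock by edgeR 4.0.16 (quasi-likelihood F test, TMM scaling) on the deposited counts at the 233 positions, a comparison chosen after seeing the data. The coverage result of 1 gene is not reported here. DESeq2 1.42.0 was the alternative. The SE of a coverage change in edgeR was back-calculated, as the absolute log2 change over the square root of its F. Coverage is known only at the listed positions, whose summed reads are not the library depth. Intervals of single-library percentages are exact (Clopper-Pearson) 95% binomial intervals from scipy 1.17.1 in Python 3.11.15, and the limit for 0 deleted reads is 3 reads of the coverage. Both cover counting error only.

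The form of the deletion model, the coverage minimum, 12 gene lists and the rule for named positions were fixed before the data were examined. Mock in place of gctrl as the reference, the spread taken from RESTART v3 alone, the lower limit on the dispersion and the choice of 1 transcript per gene came after the table was seen. The rule took the 10 positions with the largest difference, the 2 with the largest difference in each gene list, and every gene with 3 or more listed positions, with mock in place of gctrl. Its part on falls gave none, and its part on stop codons could not be applied without the transcript sequences. It named 30 positions in 25 genes. The lists were cytosolic ribosomal proteins, translation factors, nonsense-mediated decay, pseudouridine machinery, cytosolic aminoacyl-tRNA synthetases, mitochondrially encoded genes, histones, small nucleolar RNA hosts, heat shock proteins and chaperones, tubulins and actins, abundant non-coding RNA, and markers of cells foreign to a kidney-derived line. Genes covered but not listed are not known here, so no enrichment was tested. Lists with at least 5 genes were compared with the other genes by a permutation test of 100000 resamples.

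The deletion model was tested on simulated data with the real depths, and the coverage model with the mock depth in every library. The simulated spread was a fixed setting and was not fitted to these data, so the call rates need not hold for them. With a mock level lowered to the observed one, the deletion model called 200 of 200 changed positions and 3 of 135 unchanged ones. For a 1.5-fold change it called 127 of 200 and 6 of 135. The coverage model called 10 of 10 positions changed 4-fold, 7 of 10 changed 1.5-fold and 2 of 213 unchanged ones. Alternatives were coverage minimums of 10, 50 and 150 reads, Fisher's exact test, limma on the ratio, stricter lists, 1 transcript per gene, each RESTART v3 library left out, other coverage scalings, and the list without DKC1, HSPA1A and HSPA1B.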

Results

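Deletions, which the assay reads as Ψ, were compared in HEK293T cells treated with RESTART v3 (2 libraries) and in untreated cells (mock, 1 library). The question was at which cellular transcripts the treatment left off-target Ψ. Whether each deletion came from Ψ was not tested. Without gctrl values, an effect of RESTART v3 on deletions cannot be told apart from an effect of transfection. A feature of the 1 mock library alone is not excluded either. The list held 335 positions on 323 transcripts. Coverage per position ranged from 116 to 10749 reads in mock (median 281), from 108 to 10394 in RESTART v3 replicate 1 (median 258) and from 99 to 10608 in replicate 2 (median 254). Over 1 transcript per gene, 324 of 149691 mock reads (0.216%) carried a deletion, against 41807 of 160895 (26.0%) and 40758 of 159071 (25.6%) in the RESTART v3 libraries. Coverage of the 2 RESTART v3 libraries differed by more than sampling noise (chi-square 326.11 on 232 degrees of freedom, p = 4.47e-05). This argues against 1 library given under 2 names, but does not show that they came from separate cultures. The test treats positions as independent, though some may share reads, and covers counting error only. The deletion percentages of the 2 libraries did not differ by more than sampling noise (chi-square 192.883 on 233, p = 0.974), on positions whose listing limit narrows that spread.

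The highest deletion percentages lay in DKC1, the catalytic pseudouridine synthase of box H/ACA ribonucleoproteins. Its 3 listed positions reached 57.5% ± 0.207 (SD, n = 2), 55.5% ± 0.963 and 46.1% ± 0.602 in RESTART v3. In mock they had 0 deleted reads of 383, 476 and 354, which allows up to 0.783%, 0.630% and 0.847%. TMM-scaled read coverage in edgeR also rose 3.77-fold to 6.55-fold at the DKC1 positions. A transfected construct may be the source of the extra reads, so these percentages need not be those of the cellular transcript. No other listed position differed from mock by 40 points or more in the mean of both libraries. The list held 221 named genes in all, and most positions lay below 30%. Genes of ribosomal proteins, chaperones, translation factors and aminoacyl-tRNA synthetases were listed too, with means from 20.6% to 30.8%. The median difference over the list was 24.9 percentage points, 24.9 in replicate 1 and 25 in replicate 2.

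All 335 positions passed the quasi-binomial test against mock, the largest adjusted p being 4.40e-07, at CHPT1. Positions were listed because they differed by at least 20 points, so this count restates the selection. The limma-moderated dispersion was at its lower limit of 1 at every position, so the p-values of this test cover counting error only. The differences exceeded the replicate spread, whose median was an SD of 1.36 points over 233 positions, a spread that the listing limit itself narrows. At 135 of 335 positions the lower exact 95% bound was above 20% in both RESTART v3 libraries, and 30 differed from mock by 30 points or more. In mock, 209 positions had 0 deleted reads. The list repeats genes across isoforms, and with 1 transcript per gene these counts were 87, 28 and 130 of 233.

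DKC1 lies on chromosome X (154762864 to 154777689, GRCh38.p14), and the positions are 1092, 166 to 167 and 863 of transcript NM_001288747.2. Whether all reads at the DKC1 positions came from this locus was not tested. Position 1092 had 57.6% deleted of 2144 reads in replicate 1 (95% interval 55.5% to 59.8%) and 57.4% of 2073 in replicate 2 (55.2% to 59.5%). The next differences were smaller. CLEC2D, a C-type lectin gene on chromosome 12 (9669713 to 9699553), had 39.8% ± 7.06 (SD, n = 2) at position 1486 to 1487, from 135 and 154 reads. HDLBP, an RNA-binding protein gene on chromosome 2 (241227291 to 241315672), had 38.7% ± 3.66 at position 4267. RHOC, a small GTPase gene, had 36.9% ± 2.27, and LENG8 35.8% ± 4.06. The co-chaperone genes STIP1 and PTGES3 had 35.7% ± 1.88 and 35.03% ± 1.49, at 744 and 1436 reads in replicate 1. TBC1D15 had 34.8% ± 3.71. At the CLEC2D position the 2 RESTART v3 libraries lay at 34.8% and 44.8%, so its rank among these genes is not resolved.

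**Figure D1:**
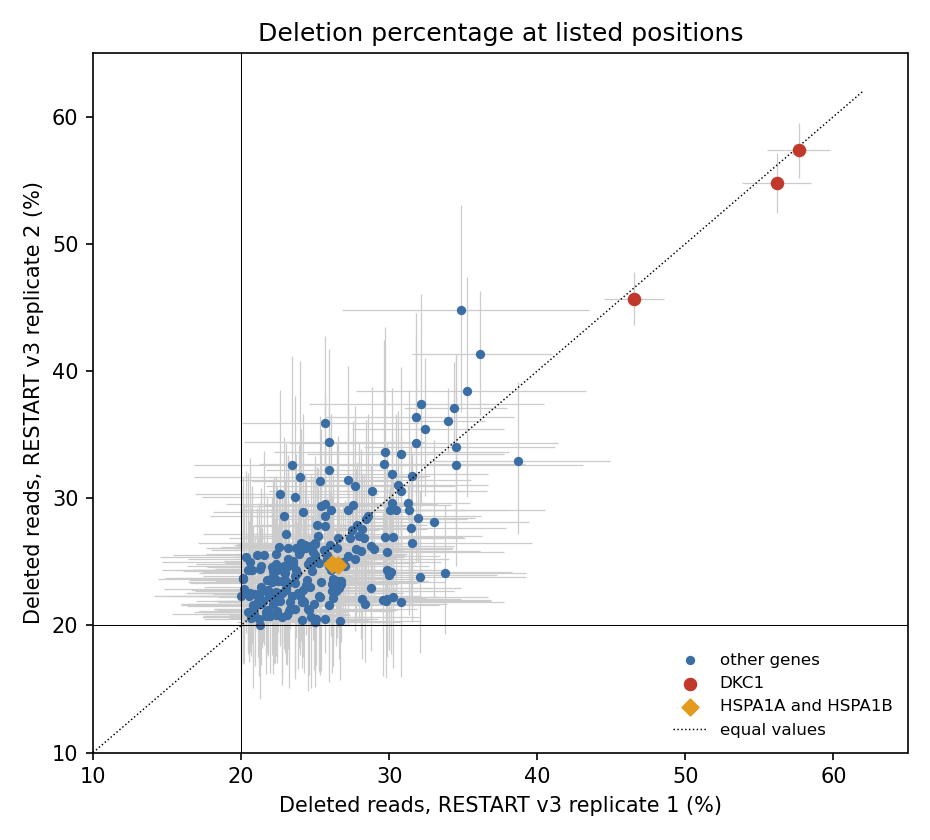
Deletion percentage in RESTART v3 replicate 1 (x axis, %) against replicate 2 (y axis, %) at 233 positions, 1 transcript per gene; bars are exact 95% binomial intervals and solid lines mark 20%. The 3 DKC1 positions (red) lie at 46.1% to 57.5%, and HSPA1A and HSPA1B (orange) at 25.6% and 25.5%, among the other genes (blue).

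Of the fixed gene lists, 5 had listed positions. Cytosolic ribosomal proteins had 6 genes (RPL10A, RPL21, RPL4, RPLP0, RPS12 and RPS24), at 20.9% to 30.4%. RPL4 was the highest, 30.4% ± 1.18 at position 491 from 5104 and 4573 reads, and RPS12 followed with 27.5% ± 0.0121. Heat shock proteins and chaperones had 9 genes (CCT2, CCT7, DNAJC7, HSP90AB1, HSPA1A, HSPA1B, HSPA5, HSPA8 and HSPD1), at 20.6% to 30.8%. DNAJC7, a J-domain co-chaperone, had 30.8% ± 0.319, and HSPA5, the Hsp70 of the endoplasmic reticulum, 29.02% ± 3.58. The mean of these lists differed from that of other genes by -0.611 points (ribosomal proteins, permutation p = 0.692, adjusted 0.956) and -0.0686 points (chaperones, permutation p = 0.956, adjusted 0.956), in 2 lists tested. The co-chaperone genes STIP1 and PTGES3 were outside the chaperone list and counted among the other genes. HSPA1A and HSPA1B counted as 2 genes, though they may share reads. The listing limit also narrows the differences that this test could find.

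Translation factors had 4 genes, EIF2S2, EIF3K, EIF4G2 and ETF1. ETF1, the release factor that recognises stop codons, lies on chromosome 5 (138506095 to 138543236) and had 29.7% ± 1.21 (SD, n = 2) at position 2934, against 0 of 150 reads in mock, which allows up to 2.00%. EIF2S2 had 22.9% ± 2.21. Among aminoacyl-tRNA synthetases, WARS1 had 24.9% ± 1.82, LARS1 23.1% ± 1.15 and AARS1 20.8% ± 0.402. DKC1 was the pseudouridine machinery gene in the list. Nonsense-mediated decay, mitochondrially encoded, histone, small nucleolar RNA host, tubulin and actin, abundant non-coding RNA and foreign cell marker genes had 0 listed positions. All entries lay on protein-coding RefSeq transcripts, and it is not known here which of these genes were covered. These zeros therefore do not show that such genes lacked off-target Ψ.

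Listing was uneven across genes. ARL6IP4 was listed on 27 transcripts, FAHD2A on 16, FAHD2B on 12, ENAH, an actin regulator, on 13 and SEPTIN2, a filament-forming GTPase, at 16 positions. With LOC124900512, these 6 genes held 86 positions, 25.7% of the list. OCIAD1, PI4KA and PLS3 were each listed on 3 transcripts. On the kept transcripts ARL6IP4 had 25.8% ± 0.242 (SD, n = 2), ENAH 25.3% ± 0.383 and FAHD2A 24.6% ± 2.05. PSMD1, a proteasome subunit, and DKC1 had 3 different positions on 1 transcript. The PSMD1 positions 1764, 1404 and 1802 to 1803 had 28.3% ± 4.30, 24.2% ± 1.41 and 23.6% ± 1.22. FAHD2A and FAHD2B, and HSPA1A and HSPA1B, are close copies, so reads could be split between them and their values are uncertain.

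Read coverage at the listed positions rose in RESTART v3 at DKC1 and at HSPA1A and HSPA1B, near-identical stress-inducible Hsp70 genes on chromosome 6 (31815543 to 31817942 and 31827738 to 31830254). HSPA1B had 988 reads in mock and 6345 and 6225 in RESTART v3, a log2 change of 2.69 (SE 0.0402, edgeR adjusted p = 9.27e-05), and HSPA1A had 357 in mock and 2386 and 2238, a log2 change of 2.71 (SE 0.0538, edgeR adjusted p = 0.000147). At DKC1 the log2 changes were 1.91 (SE 0.0342) at position 166, 2.48 (SE 0.0375) at 1092 and 2.71 (SE 0.0401) at 863, with edgeR adjusted p-values of 0.000125, 9.27e-05 and 9.27e-05. These genes were chosen for coverage after their values were seen. The SEs, back-calculated from F, lie below what counting error alone would give at these read numbers, so they overstate the precision.

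Of 233 positions, 7 passed as higher and 1 as lower in edgeR, against 8 and 39 without TMM scaling, which moved the median log2 change from 0.02 to -0.10. Without TMM, coverage was scaled to the summed reads at these positions, 149691 in mock and 160895 and 159071 in RESTART v3. The risen reads of DKC1, HSPA1A and HSPA1B are part of those sums and so lower every other position. Calls of lower coverage without TMM are therefore not evidence of a fall. Besides the 5 positions in these 3 genes, ATF4, a stress-response transcription factor, and ATP5PO passed as higher (log2 changes 0.28 and 0.26, edgeR adjusted p = 0.0460 and 0.0494). In DESeq2 ATF4 and ATP5PO did not pass (adjusted p = 0.299 and 0.653). Of the 9 chaperones, 2 rose and 7 did not pass with TMM scaling, and 3 were higher and 1 lower adjusted over the list alone. Without TMM, 4 of them passed as lower, HSPA8, CCT7, CCT2 and HSPA5. HSPA5 had a log2 change of -0.41 (SE 0.173, edgeR adjusted p = 0.289) with TMM and -0.52 (edgeR adjusted p = 0.0437) without, and HSPA8 -0.25 (edgeR adjusted p = 0.129) and -0.37 (edgeR adjusted p = 0.000252). HSP90AB1 had 0.21 with TMM (edgeR adjusted p = 0.0846 over all positions) and 0.10 without, and passed as higher, as HSPA8 did as lower, adjusted over the list alone (edgeR adjusted p = 0.0112 and 0.0336). HSPD1 had 0.02 with TMM and -0.09 without, passing in neither. The 6 ribosomal protein positions did not pass with TMM, also adjusted over the list alone, whereas 4 (RPL4, RPS24, RPL10A and RPL21) passed as lower without it. The 3 synthetase positions did not pass with or without TMM. Of the 4 translation factors, 0 passed with TMM over all positions and 2 were higher adjusted over the list alone, while without TMM 1, EIF4G2, passed as higher (log2 change 0.13, edgeR adjusted p = 0.0371). With 1 mock library, the spread comes from the RESTART v3 pair alone.

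**Figure D2:**
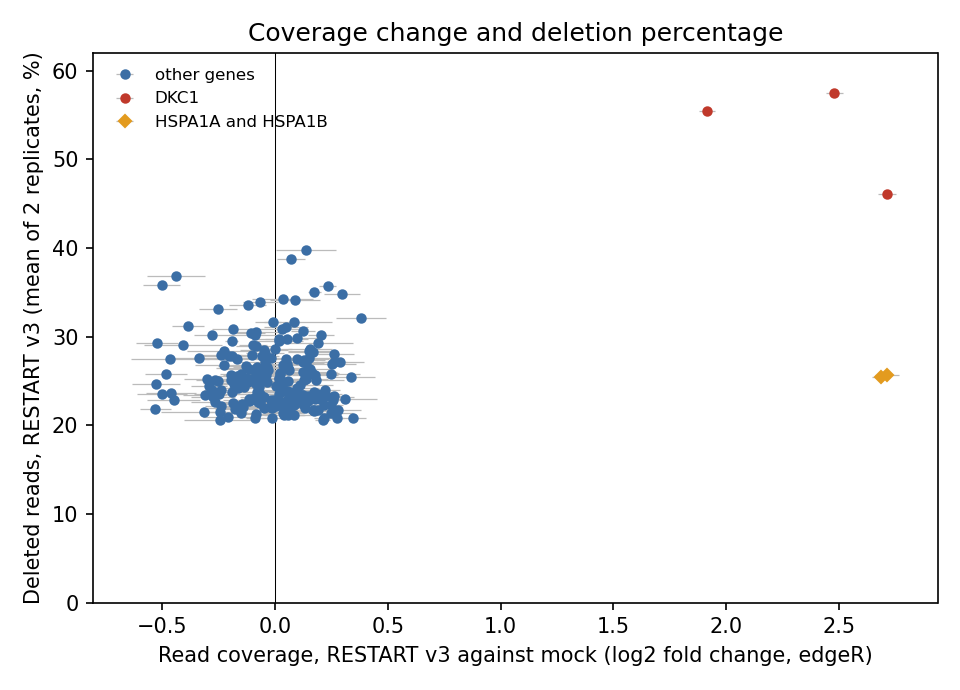
Log2 change of read coverage, RESTART v3 against mock (x axis, edgeR, bars are SE back-calculated from F), against the mean deletion percentage of 2 RESTART v3 libraries (y axis, %) at 233 positions. DKC1 (red) and HSPA1A and HSPA1B (orange) lie at log2 changes of 1.91 to 2.71, and DKC1 also at 46.1% to 57.5% deletion.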

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

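The tests in this part were chosen after the coverage values of RESTART v3 and mock were seen. The one on transfection needed gctrl values and could not be run. The reads covering a position are outside the main measurement, the deletion percentage, and in 3 genes they stood above mock under edgeR with and without TMM scaling and under DESeq2. The TMM-scaled coverage of RESTART v3 over mock in edgeR was 3.77-fold at DKC1 position 166, 5.57-fold at 1092 and 6.55-fold at 863. It was 6.44-fold at HSPA1B position 1946 and 6.55-fold at HSPA1A position 1947. As an unscaled ratio of reads it was 3.73 at DKC1 position 166, and at 228 other positions that unscaled ratio had a median of 0.992 and ranged from 0.685 to 1.29.

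DKC1 combined the highest deletion percentages with this rise. If every extra DKC1 transcript lacked the base, the deletion percentage would equal the share of extra reads, which was 73.5%, 84.7% and 82.0% at positions 166, 863 and 1092. The upper 95% bounds were below those shares by 15.01 points or more, which argues against this explanation. More coverage alone is argued against by HSPA1A and HSPA1B, whose highest upper bound was 28.4%, below the lowest DKC1 bound of 43.6%. A base missing from part of the extra transcripts, Ψ on them, and a transfected construct as their source may each still apply, and neither the plasmid contents nor the sequence was used here.

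HSPA1A and HSPA1B, the stress-inducible Hsp70 genes, rose under each scaling, while calls of the other listed chaperones depended on the setting. HSP90AB1 passed as higher and HSPA8 as lower adjusted over the list alone with TMM. HSPA8, CCT7, CCT2 and HSPA5 passed as lower over all positions without TMM, a scaling in which the risen genes lower every other position. A difference in library depth is argued against by the 95th percentile of the unscaled ratio at the other positions, 1.18. Reads moved from one copy to the other are argued against by the reads summed over both genes, which were, unscaled, 6.29 and 6.49 times the 1345 mock reads. A response to transfection of any plasmid and a response to RESTART v3 cannot be told apart, since 0 gctrl libraries had values here, and a feature of the 1 mock library alone is not excluded.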

How the results depend on the processing

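Apart from the coverage minimums of 10 and 50 reads, Fisher's exact test, the gene list counts and the single libraries at named positions, the alternatives here were chosen after seeing the data. The 335 positions higher than mock stayed 335 in Fisher's exact test and in limma, which restates the selection, as they were listed for that difference. Minimums of 10 and 50 reads removed no position, the lowest coverage being 99 reads, and so test nothing. The positions numbered 285 at 150 reads, 233 with 1 transcript per gene and 330 without DKC1, HSPA1A and HSPA1B. Stricter lists, fewer by construction, left 30 (difference of at least 0.3) and 135 (lower bounds above 20%). The median difference of 24.9 points was 24.9 to 25 with 1 RESTART v3 library left out, 25.6 as a mean, 24.7 with 1 transcript per gene and 32.4 in the list of at least 0.3, which held 5 of the 25 positions in gene lists. All 60 single-library values at 30 named positions kept their direction. The listing limit on the difference held in each RESTART v3 library, so none could reverse and this check tests nothing. Positions with higher coverage (7) numbered 5 in DESeq2, 8 without TMM, 5 over all listed positions, 8 at 150 reads and 0 in edgeR without DKC1, HSPA1A and HSPA1B (19 at an unadjusted p under 0.05). Those with lower coverage (1) numbered 0 in DESeq2 (6 unadjusted), 39 without TMM, 0 over all positions (52 unadjusted), 3 at 150 reads and 0 without those genes (20 unadjusted). The scaling without TMM counts the risen reads of those genes, which lowers the other positions. The cause of the other changes in number was not tested. No paired analysis was possible because mock has 1 library and gctrl is not analysed here. For the same reasons the alternatives to the gctrl comparisons and counts with a library left out (no residual degrees of freedom) were not run, nor those of the sequence and region questions. Depth limits the shallow positions: the median was 27.2% at 37 positions under 150 reads and 24.5% at 196 others, and the minimum of 30 deleted reads alone raises the former.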

Other observations

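The genes in this part were chosen after their values were seen. YBX1, an mRNA-binding cold-shock protein, had 31.7% ± 0.130 (SD, n = 2) at position 312, from 6262 and 6254 reads. NPM1, the nucleolar chaperone nucleophosmin, had 22.9% ± 0.787 from 10394 and 10608 reads, and nucleolin (NCL) 22.8% ± 0.968. NOP58, a core protein of box C/D ribonucleoproteins, had 25.8% ± 1.65, and WTAP, a subunit of the m6A methyltransferase complex, 25.2% ± 1.23. HBS1L, a factor that rescues stalled ribosomes, had 25.8% ± 5.41. Among proteasome genes PSMD7 had 30.7% ± 0.188 and PSMD2 26.2% ± 0.244 and 22.9% ± 2.36 at positions 494 and 688. COPS2, a COP9 signalosome subunit, had 34.3% ± 0.344.

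The repeated listing of single genes was tested, after the repeated values were seen, as reads shared between transcripts of 1 gene. Sharing of reads between paralogs, such as FAHD2A and FAHD2B, was not tested. Deleted reads of different transcripts of 1 gene varied less than separate reads would, with a pooled chi-square of 50.4 on 196 degrees of freedom, a ratio of 0.257 where separate reads from equal ratios would give about 1. This is consistent with the same reads being counted on several transcripts, so positions of 1 gene, such as the 27 of ARL6IP4, may be fewer separate sites than entries. The listing limit also narrows the spread, by an amount not tested. The FAHD2A, FAHD2B and LOC124900512 positions had means of 22.8% to 25.5%, and their unscaled coverage ratio had a median of 0.698, with edgeR adjusted p-values of 0.126, 0.129 and 0.147 with TMM and 0.00835, 0.0110 and 0.0157 without it.

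Positions given as 1 nucleotide (120) had a median of 25.3% and wider ones (113) 24.0%, and the means differed by 1.15 points (permutation p = 0.0649).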
